A study of Mus musculus with 3 samples.

How the data were processed

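Cells of the mouse subfornical organ were measured by droplet single-cell RNA sequencing in 1 sated and 2 sodium-depleted samples. Per the labels' protocols, mice were anaesthetized with isoflurane, the tissue was digested with papain, actinomycin-D in the buffers blocked the induction of immediate early genes during preparation, and libraries followed the 10x Genomics 3' v3.1 protocol. The labels give equal use of both sexes and 15 to 20 animals per condition, and record no injection for the sated animals. Cell Ranger 6.1.2 and the mouse build mm10 are named in the submitters' processing notes, without further settings, so filters on cells and genes, the treatment of intronic reads and the removal of free RNA or doublets are not stated.

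The deposited values are raw counts of unique molecular identifiers (UMIs) per gene and cell. All values tested were whole numbers, and totals differed from cell to cell, starting at 500 UMIs in the all-cell tables and near 1000 in the neuron tables. The authors' neuron tables are a subset of the all-cell tables with the same counts in every cell, and how neurons were chosen is not stated. The tables hold 45436 cells, of which 7819 are neurons, and 30801 genes given by symbol. Name prefixes give each depleted cell its replicate and divide the sated cells into 2 sets, which were summed as 1 library in the main tests. At a floor of 3 counts, a gene without UMIs in neurons lies below 0.3112 and 0.0697 CPM in sated sets 1 and 2 and below 0.2073 and 0.0776 in depleted replicates 1 and 2. Intervals and floors cover counting error only.

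Everything from here on was computed from these counts. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, leidenalg 0.10.2 and matplotlib 3.10.9 was used, with R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0 for the tests. No cell of the tables was left out in the main results. Cells were clustered on log-normalized counts of 2000 variable genes, leaving out the immediate early, late activity, heat shock, mitochondrial, ribosomal, Xist and Y-linked genes. Genes were centred per cell set, and 30 principal components, 6 neighbours from each cell set and the Leiden method at resolution 0.6 (all cells) or 1.0 (neurons) were used. A cluster took a cell type's name with the ending "-like" when at least 3 markers from a fixed list were detected at 30 CPM, their mean log2 enrichment was at least 1 and no other type had markers among the 10 leading genes in a number equal to or above its own. A cluster of low depth also needed a marker of its own among these 10. Other clusters kept a number. Neuron clusters formed a GABAergic-like class by the fixed markers and Slc32a1 without Slc17a6. The fixed glutamatergic markers had under 3 detected members, so the other class was defined by Slc17a6 and Etv1 without Slc32a1, each at 30 CPM. Neuron clusters with at least 50 cells and cell classes with at least 100 cells in each group were compared.

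UMIs were summed over the cells of a library in each cluster, class or all neurons. The main test was the edgeR quasi-likelihood test of 1 sated against 2 depleted sums, with filterByExpr and TMM factors, a Benjamini-Hochberg adjusted p of 0.05 and 1 residual degree of freedom. DESeq2 was run on the same sums for genes with at least 10 counts. All tests were 2-sided. Changes given with a standard error are edgeR's log2 changes. The standard error was derived as the absolute log2 change over the square root of the test's F statistic. It is not a measured spread between libraries. Ratios and CPM (the UMIs of a gene scaled to a common total of UMIs) use the total UMIs of the unit. Ratios carry exact conditional binomial (Clopper-Pearson) intervals at 95%, shares exact binomial ones. A gene passed the rule of size when its log2 ratio was at least 1 or at most -1, the higher group had at least 20 CPM and the interval excluded 1. Mitochondrial, ribosomal, haemoglobin, Xist and Y-linked genes were counted apart. Against a group with no UMI the fold was taken from 3 counts over the group and given as a lower bound.

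The 17 gene lists were fixed before the data were examined. They are immediate early, late activity response, dissociation and heat shock, glucocorticoid response, circadian clock, renin-angiotensin with aldosterone and sodium handling, prostaglandin synthesis and receptors, neuropeptides, receptors of circulating signals, cholesterol synthesis, interferon response, nuclear oxidative phosphorylation, mitochondrially encoded, synaptic vesicle and release, voltage-gated channels, microglial activation, and hypoxia and vascular signalling. Some genes stand on more than 1 list, such as Cdkn1a and Per1. A list's value is the median log2 ratio of members with at least 1 CPM in a group, with its percentile among 10000 random lists of the same size and matched expression. Members were also tested with the adjustment over the list alone. Genes were named by a fixed rule. In neurons these were the 12 highest and 12 lowest genes past the rule of size and the adjusted p, which gave 0 genes, and in other units the 5 highest and 5 lowest. The 4 members of each list with the largest absolute log2 ratio in neurons and Fos, Agtr1a, Ptger3, Rxfp1, Pdyn, Slc17a6, Gad2 and Xist were always included. Other list members were read from their lists, and other genes were chosen after their values were seen.

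After neurons of sated set 1 were seen to correlate better with depleted replicate 1 than with sated set 2, values within each set number, sums with equal weight per set and fits with the sated sets as 2 libraries, with and without the set number as a block, were added. An edgeR test of the difference between a neuron cluster and all other neurons of the same libraries (library, cluster, and cluster by condition) was added at the same time. It counts cluster and remaining neurons of a library as separate sums, and was repeated with the cells of cluster 10 left out of the remaining neurons. With the sated cells as 1 library, its residual spread also comes from the depleted libraries alone.

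The main edgeR test, DESeq2 and the rule of size were run on simulated data. These had the real means and totals, the spread between the depleted libraries and 200 changed genes. For all neurons edgeR recovered 9 of 50 genes changed 2-fold, 49 of 50 changed 4-fold and 50 of 50 changed 16-fold or 64-fold among 17546 genes, with 36 false calls. DESeq2 recovered 6, 48, 50 and 50 among 18875 genes, with 30 false calls, and the rule of size 29, 50, 50 and 50 among 30801 genes, with 157. For cluster 10 edgeR recovered 10, 40, 50 and 50 at the same 4 fold sizes among 11916 genes, with 11 false calls. DESeq2 recovered 2, 19, 49 and 48 among 13110 genes, with 3 false calls, and the rule of size 23, 49, 50 and 50 among 30801, with 272. The rule of size alone therefore passes unchanged genes when libraries vary, and its counts are given as descriptions. False calls also exceeded the share allowed by the adjusted p threshold in simulated neurons, with 36 by edgeR and 30 by DESeq2. In simulated cluster 10 the 11 by edgeR exceeded it slightly, and the 3 by DESeq2 did not. Adjusted p-values in neurons, and those of edgeR in cluster 10, may thus be too low. The test of the difference from other neurons and the fits with a set-number block were not run on simulated data.

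Other choices tried were TMM and median-of-ratios scaling, totals without technical genes, minimums of 50, 5 and 0 CPM, 1.5-fold, equal weight per cell, and cells with at least 1000 genes. Predicted doublets were left out by Scrublet as implemented in scanpy, at 0.8% per 1000 cells because its own threshold marked between 0% and 6.76% of a set. Neurons were thinned to 3000 UMIs and other cells to 1000, which left out 104 sated and 71 depleted neurons and 1761 sated and 2814 depleted cells below these depths. Lower and higher resolution, neuron-like clusters in place of the authors' neuron tables, each depleted replicate left out, and clustering again without 503 genes at least 2-fold different in cluster 10 completed the set. Gene positions were looked up by symbol in GENCODE vM21.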

Results

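Single-cell RNA was measured by 10x Genomics 3' v3.1 sequencing in the subfornical organ, a small forebrain structure outside the blood-brain barrier that senses circulating signals of salt and water balance. C57BL/6 mice of 7 to 8 weeks were either sated, with free food and water, or sodium depleted by furosemide, a diuretic that drives sodium loss, at 50 mg/kg and 1 day of low-sodium diet. The sated group was 1 GEO sample and the depleted group 2 replicate libraries. Each condition pooled 15 to 20 animals, so the replicates are separate libraries, and cells are not replicates. With 1 sated library, p-values of the main test rest on the spread between the 2 depleted libraries. No spread among sated libraries enters them. The sated table held cells under 2 name prefixes, called sated sets 1 and 2, and the labels do not say how they were made. All cells numbered 11578 and 6785 in sated sets 1 and 2 and 13252 and 13821 in depleted replicates 1 and 2. Their UMI totals were 56310558, 87585004, 71487684 and 106026262. The authors' neuron tables held 1325, 2055, 1764 and 2675 of these cells, with 9640335, 43061441, 14468855 and 38657264 UMIs and median UMIs per neuron of 6918, 20452, 7715 and 13722.

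Across 7796 genes, which are not independent replicates, the UMI profiles of neurons had a Spearman correlation of 0.989 between sated set 1 and depleted replicate 1 and of 0.875 between the sated sets. The depleted replicates correlated with each other at 0.934, and sated set 2 with depleted replicates 2 and 1 at 0.923 and 0.89, so that neither condition nor set number alone orders the sets. Values within set number 1 (depleted replicate 1 against sated set 1) and set number 2 (replicate 2 against set 2) stand beside many of the pooled ones. Levels are given as CPM, the UMIs of a gene over the UMIs of its group of cells, scaled to a common total. Intervals are 95% and cover counting error only.

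The first comparison asked which genes differ between all neurons of sodium-depleted and sated animals, the stimulus side of the design. Fos, the immediate early gene most used to mark recently active neurons, was at 11.2 CPM in sated and 14.9 in depleted neurons, a ratio of 1.34 (1.20 to 1.49), with 1.92 (1.46 to 2.54) and 1.265 (1.12 to 1.43) within set numbers 1 and 2. Neuron cluster 10, described below, supplied 5 of the 589 sated and 255 of the 794 depleted Fos UMIs, and without its cells, a choice made after the data were seen, the ratio was 0.918 (0.815 to 1.03). In the neuron-like clusters of the all-cell tables it was 1.05 (0.946 to 1.175). These leave out an unnamed cluster led by C1ql1 and Bdnf, of whose cells 81.8% are in the authors' neuron tables. That cluster may hold most cells of neuron cluster 10, so this ratio is not independent of the one without cluster 10. Bdnf, a secreted growth factor made in active neurons, was at 19.9 in sated and 61.4 in depleted neurons, a ratio of 3.09 (2.88 to 3.32), with log2 ratios of 1.75 and 1.68 within set numbers 1 and 2. Anxa2, which encodes a calcium-dependent membrane-binding protein, had a ratio of 5.94 (5.09 to 6.96), with log2 ratios of 1.16 and 2.99 within the set numbers, and Cartpt, the precursor of a feeding-related peptide, one of 2.32, with 0.46 and 1.43. Rxfp1, the relaxin receptor, was at 244.7 CPM in sated and 104.1 in depleted neurons, a log2 ratio of -1.23, with -0.57 and -1.30.

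With 1 sated library against 2 depleted ones, edgeR called 0 of 17768 genes in neurons, with 444 at an unadjusted p under 0.05. DESeq2 called 4 on the same sums, 3 higher and 1 lower, namely Anxa2 (adjusted p 0.017), Gm26870 (7.33e-04) and Gm15489 (0.036) higher and Gm28153 (0.0108) lower. Fits with the sated sets as 2 libraries count more sated libraries than the 1 sample in the labels. Without a block, such a fit by edgeR called 0 of 16655 genes. With the set number as a block, a model chosen after the data were seen, edgeR called 154 genes, 130 higher and 24 lower. Under that model Bdnf rose (adjusted p 5.48e-13, against 0.999 by edgeR and 0.643 by DESeq2 on the main sums), as did Anxa2 (1.82e-12), Cartpt (6.62e-04), Sst (3.44e-04) and Mfge8 (1.37e-04). Sp110 fell (1.95e-08) and so did Car1 (0.00184), while Rxfp1 had an adjusted p of 0.0783. These genes were at an edgeR adjusted p of 0.999 on the main sums, and those outside the fixed lists were chosen after their values were seen.

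By size alone, 66 genes were at least 2-fold different at 20 CPM or more, 40 higher and 26 lower in depleted neurons (59 and 9 with TMM factors, 59 and 8 with median-of-ratios factors, so that the lower count depends on the scaling), 13 further ones being mitochondrial, ribosomal, haemoglobin or sex-linked genes. Only Bdnf, Anxa2 and the gene model AY036118 of the higher genes, and Sp110 of the lower ones, passed 2-fold within both set numbers. Several of the higher genes were high in depleted replicate 2 alone. Cmss1 was at 170 and 114 CPM in sated sets 1 and 2, 183 in depleted replicate 1 and 3173 in replicate 2, and Gphn at 345, 364, 367 and 2846 in the same order. Camk1d, at 37.5 in replicate 1 and 489 in replicate 2, and Lars2, at 54.9 and 576, had the same order of libraries. The median log2 ratio of all genes past the minimum was -0.13 with scaling by total UMIs and -0.02 with TMM factors, so values near -0.1 lie at the centre of all genes. Without depleted replicate 1 the number past this rule was 105, and without replicate 2 it was 287.

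Of the 17 fixed gene lists, none had a member called by edgeR in all neurons, over all genes tested or adjusted over the list alone. The immediate early genes had a median log2 ratio of 0.08 over 15 measured members, at percentile 92.3 of random lists matched on expression, and 0.32 and 0.03 within set numbers 1 and 2. Without the cells of cluster 10 that median was -0.22. In the neuron-like clusters, which leave out the unnamed cluster led by C1ql1 and Bdnf, it was -0.06. Egr1 and Junb, which encode transcription factors, were at 1.08 and 13.3 CPM in sated and 3.63 and 19.9 in depleted neurons, whereas the synaptic gene Arc was at 8.52 and 4.88. Late activity genes had a median of 0.25 (percentile 98.7), and 0.29 and 0.35 within the set numbers. In that list Vgf, a secretory-granule peptide precursor, had a ratio of 1.64, and the cell-cycle inhibitor Cdkn1a was at 5.48 and 12.5 CPM. Neuropeptide genes had a median of 0.29 (percentile 99.3), but -0.22 and 0.44 within set numbers 1 and 2. Sst, the somatostatin precursor, was at 4.02 and 14.3 CPM.

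The receptors of circulating signals had a median log2 ratio of -0.38 (percentile 0.68) in neurons, -0.02 and -0.40 within set numbers 1 and 2. Rxfp1 and Rxfp3 had the 2 lowest values named there, with log2 ratios of -1.23 and -1.02, while Agtr1a, the angiotensin II receptor, was at 40.2 CPM in sated and 29.9 in depleted neurons. The prostaglandin list had a median of -0.12 (percentile 42.9), and its receptor Ptger3 was at 10.1 and 8.15. Renin-angiotensin, aldosterone and sodium handling genes had a median of 0.01 (percentile 72.1), with Agt, the angiotensin precursor, at a log2 ratio of 0.87 and the mineralocorticoid receptor Nr3c2 at -0.47. Glucocorticoid response genes had a median of 0.22 (percentile 99.5), and 0.37 and 0.13 within the set numbers. Circadian clock genes were at 0.11 (97.6), cholesterol synthesis genes at -0.16 (40.7), microglial activation genes at 0.13 (71.7) and hypoxia and vascular genes at -0.02 (67.0).

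Several list medians in neurons came from set number 2. Mitochondrially encoded genes had a median log2 ratio of -0.93 (percentile 0), with 0.16 and -1.11 within set numbers 1 and 2. Voltage-gated channels were at -0.34 (0.78), with 0.07 and -0.39. Synaptic vesicle genes were at -0.28 (2.47), with 0.06 and -0.35, and Vamp2, the vesicle fusion protein, was at 639.9 CPM in sated and 330.5 in depleted neurons. Dissociation and heat shock genes were at -0.32 (2.64), with 0.17 and -0.42. Nuclear genes of oxidative phosphorylation were at 0.32 (99.6), with -0.19 and 0.55, and interferon response genes at 0.35 (99.1), with -0.49 and 1.23. Of the genes always reported, Pdyn was at 42.6 CPM in sated and 42.4 in depleted neurons, Slc17a6 at 41.9 and 46.2, Gad2 at 312.5 and 379.8, and Xist, a check of the balance of sexes, at 378 and 410.

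The next comparison asked which neurons carry the immediate early response. Neurons fell into a class with GABA synthesis and transport genes (1658 sated and 2125 depleted cells) and one with the vesicular glutamate transporter gene Slc17a6 and the transcription factor gene Etv1 (1508 and 1976 cells). The GABA synthesis gene Gad2 did not separate them. Its mean CPM per cell was 623.6 and 731.3 in clusters 9 and 10 of the second class and 29.2 in its cluster 3, against 358.4 in GABAergic-like cluster 1. In the second class Fos was at 4.25 CPM in sated and 11.03 in depleted cells, a ratio of 2.60 (2.11 to 3.21), with 2.75 and 2.59 within set numbers 1 and 2. Its immediate early genes had a median log2 ratio of 0.27 (percentile 98.8; 0.27 and 0.21 within the set numbers) and its late activity genes one of 0.40 (99.9). Without the cells of cluster 10 Fos in the pooled rest of the class had 124 sated and 76 depleted UMIs, a ratio of 0.624 (0.463 to 0.837), and the immediate early median was -0.27. The immediate early medians of single clusters in that rest were not stable, at 0.44 in cluster 8 but -0.03 within set number 1, and 0.30 in cluster 9 but -0.05 without depleted replicate 2. In the GABAergic-like class Fos had a ratio of 0.976 (0.847 to 1.13), with 1.71 and 0.907 within the set numbers, and the immediate early genes a median of -0.08 (60.4; 0.41 and -0.18). Median-of-ratios scaling turned that last median to 0.04. By edgeR, 0 of 16318 genes were called in the Slc17a6-Etv1 class (545 at an unadjusted p under 0.05, 4 by DESeq2) and 0 of 15493 in the GABAergic-like class (360 and 5). With the sated sets as 2 libraries and the set-number block edgeR called 16 and 108, against 0 and 0 without the block. Adjusted over the list alone, 3 late activity genes passed in the Slc17a6-Etv1 class.

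Within the Slc17a6-Etv1 class, neuron cluster 10 held the largest Fos ratio of the 12 clusters with enough cells. It made up 4.75% and 4.67% of the neurons of sated sets 1 and 2 and 4.59% and 4.37% of those of depleted replicates 1 and 2, 159 sated and 198 depleted cells. Its sated cells were led by C1ql1, Sncg, Fam19a1 and Ptger3, a prostaglandin E2 receptor, and Agtr1a was at 163 CPM against 40.2 over all sated neurons. Fos rose from 5 to 255 UMIs, 1.92 to 92.5 CPM, a ratio of 48.1 (20.4 to 150) and an edgeR log2 change of 5.59 ± 0.532 (SE, n = 1 and 2 libraries, adjusted p 0.00789). The ratio was 17.3 (4.58 to 146) and 70.7 (23.9 to 346) within set numbers 1 and 2, 30.4 with cell sets weighted equally and 32.1 with cells thinned. Vgf rose from 7.69 to 603 CPM, by 6.44 ± 0.542 (0.00599), and Cdkn1a from 1.54 to 106, by 6.05 ± 0.594 (0.00789). The other 4 genes that edgeR called were Cited1, a transcriptional coregulator, Mfge8, a secreted adhesion protein, Pnoc, the nociceptin precursor, and Fam46a. Cited1 rose by 3.94 ± 0.514 (0.0382), Mfge8 by 3.999 ± 0.438 (0.0122) and Pnoc by 3.83 ± 0.463 (0.0238), and Fam46a, with no UMI in sated cells, was at least 31.5-fold higher (0.0107). Pnoc and Mfge8 were chosen after their values were seen. Pnoc and Fam46a were also among the leading genes of GABAergic-like neuron cluster 5, and Pnoc of cluster 2. Cited1 was among those of unnamed cluster 10 of all cells, with Gad1 and Slc32a1. Free RNA from other neurons was not measured.

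These 7 genes were all that edgeR called among 11996 in cluster 10, with 940 at an unadjusted p under 0.05, and each was at least 2-fold higher within both set numbers. With the sated sets as 2 libraries and the set-number block edgeR called 400, 253 higher and 147 lower, against 6 without the block. DESeq2 called 18, all higher, including Bdnf (1.02e-06), Anxa2 (1.05e-07) and Cartpt (3.56e-04). By size alone 536 genes passed, 216 higher and 320 lower, but 271 and 219 with TMM factors and 316 and 184 with median-of-ratios factors, so that which direction holds more genes depends on the scaling. Simulated libraries with no change in most genes gave 272 such false calls. Of the 536, 107 higher and 87 lower ones passed 2-fold within both set numbers, and without depleted replicate 2 the number was 976. A UMI of Fos was seen in 4 of 159 sated cells (2.52%, exact interval 0.690 to 6.32) and 97 of 198 depleted ones (49.0%, 41.8 to 56.2), at median depths of 16035 and 14357.5 UMIs. The share was 6.30% and 6.38% in ependymal-like cells, at median depths of 8815 and 6805 UMIs, and 10.8% and 9.96% over all neurons. Thinned to 3000 UMIs per cell, the shares in cluster 10 were 1.29% and 20.2%.

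**Figure D1:**
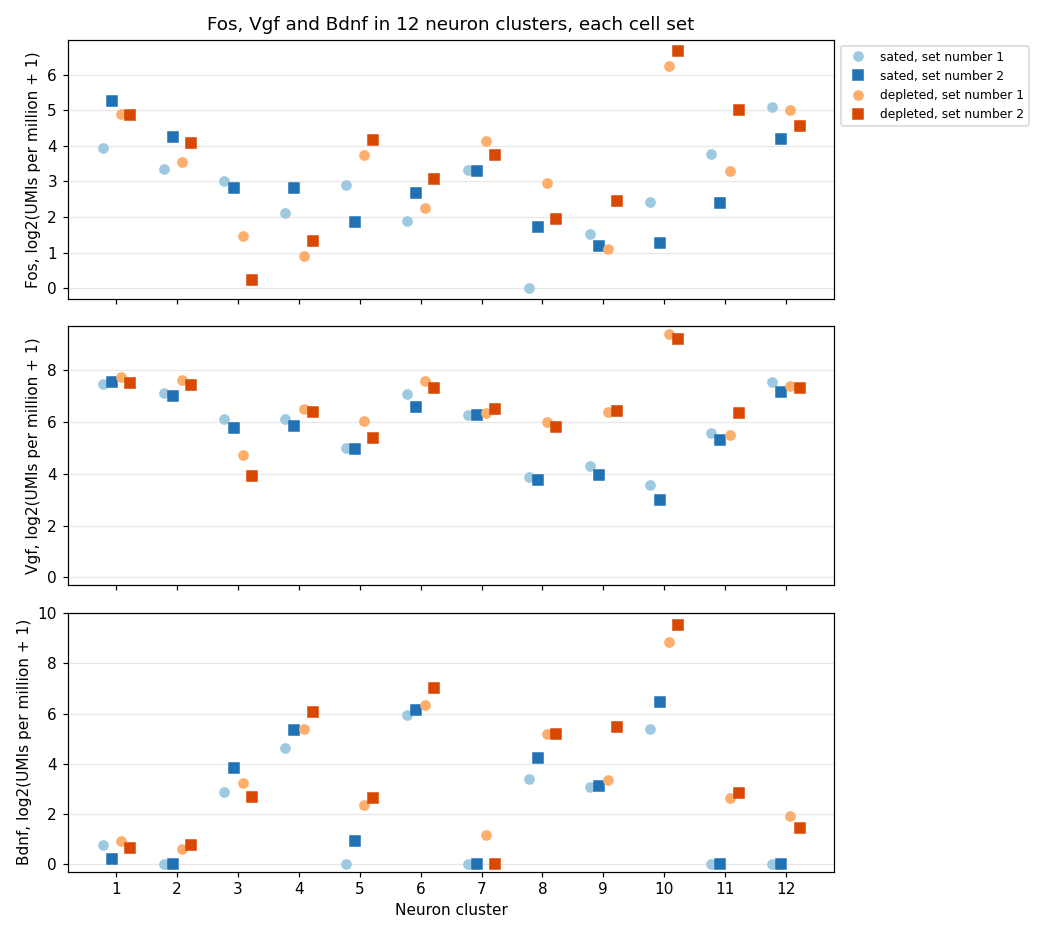
Fos, Vgf and Bdnf as log2 of CPM plus 1 in each of the 12 neuron clusters, 1 point per cell set (circles for set number 1 and squares for set number 2, blue for sated and orange for depleted). In cluster 10 both depleted sets lie above both sated sets for all 3 genes, whereas in cluster 3 Fos and Vgf lie lower in both depleted sets.

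Set against all other neurons of the same libraries, 663 of 16003 genes changed differently in cluster 10, 362 more upward and 301 more downward, by an edgeR test of the difference that was chosen after the data were seen. Of its 15 measured immediate early genes 13 were higher by their counting intervals and 0 lower, with a median log2 ratio of 2.24 (1.14 and 2.22 within set numbers 1 and 2). By edgeR 1 was called over all genes and 11 of 14 tested were called adjusted over the list alone, and 8 and 11 rose more than in other neurons. Fosl2 had a ratio of 13.2 (4.88 to 50.2), Nr4a1 one of 4.91 and Ier2 one of 3.39, and each rose more than elsewhere (1.48e-05, 2.72e-05 and 1.48e-05). Jun, at 60.0 and 62.4 CPM, and Junb, at 24.98 and 53.7 (adjusted p of the difference 0.404), were not called. Late activity genes had a median of 1.47 (1.28 and 1.93 within the set numbers), with 2 called over all genes and 6 of 12 adjusted over the list alone, and 6 beyond other neurons. Bdnf was at 78.8 and 669 CPM, a ratio of 8.49 (7.35 to 9.86), with an edgeR adjusted p of 0.0771 and a difference from other neurons of 2.37 ± 0.171 (1.77e-39). Pcsk1, the enzyme that cleaves peptide precursors, had a ratio of 7.50 (5.39 to 10.7), Crem, a cAMP-responsive transcription factor gene, 5.11 (4.29 to 6.12), and the granule protein gene Scg2 4.79 (4.56 to 5.04).

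Neuropeptide genes in cluster 10 had a median log2 ratio of 1.27 (0.79 and 1.55 within set numbers 1 and 2), with 0 called over all genes and 6 adjusted over the list alone. The difference from other neurons was past the threshold for 5, over all genes and adjusted over the list alone. Adcyap1, the precursor of the peptide PACAP, was at 193 and 723 CPM (difference 2.59, 9.74e-60), Trh at 43.1 and 134 (1.61, 6.40e-13) and Gal, the galanin precursor, at 4.997 and 25.8 (2.20, 9.15e-06). Cartpt was at 4.997 and 64.2 CPM, a ratio of 12.9 (7.32 to 24.6). The galanin receptor gene Galr1, chosen after its values were seen, had 1 and 68 UMIs, a ratio of 64.2 (11.1 to 2572). Gad2, a GABA synthesis enzyme, was at 440.5 and 1015 (difference 0.98, 2.10e-08). Ptger3 was at 144.5 and 108 CPM, Agtr1a at 163 and 127, Slc17a6 at 115 and 152, Pdyn at 80.3 and 100.5 and Xist at 269 and 247, and Rxfp1 had 3 and 11 UMIs.

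Cholesterol synthesis genes in cluster 10 had a median log2 ratio of -0.84 (-0.87 and -0.81 within set numbers 1 and 2), below all 10000 random lists. Of 15 measured members 11 were lower and 0 higher by their intervals. By edgeR 0 were called, over all genes or adjusted over the list alone, and 7 and 11 fell more than in other neurons. Insig1, a sensor of sterol levels, was at 114 and 47.9 CPM (difference -0.77, 0.00459), Hmgcs1, an early enzyme of the pathway, at 214.5 and 112 (-0.65, 0.00213), and Fdft1 at 156 and 87.1 (-0.74, 8.34e-04). Circadian clock genes had a median of -0.21 (-0.40 and -0.12), with 0 called over all genes and 3 adjusted over the list alone, and 4 and 5 fell more than in other neurons. Dbp, a clock output factor, was at 229 and 64.6 (difference -2.11, 1.73e-31), Bhlhe41 at 223 and 70.0 (-1.95, 1.65e-27) and Per3 at 65.4 and 21.0 (-1.89, 2.13e-11). Glucocorticoid response genes had a median of 0.51 with 1 call, Cdkn1a, which is also on the late activity list. Mitochondrially encoded genes were at -1.12, with -0.04 and -1.30 within the set numbers.

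**Figure D2:**
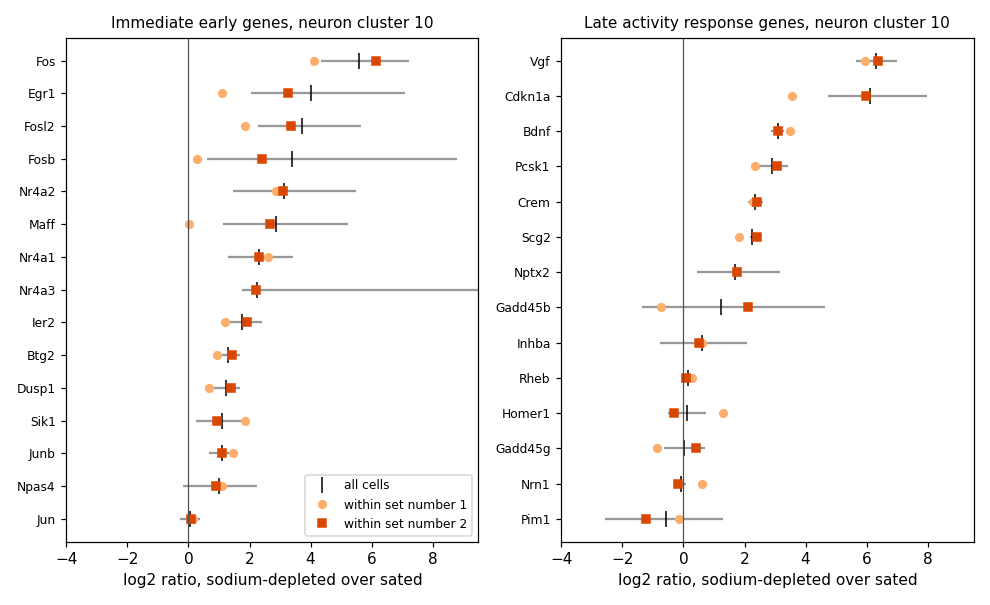
Log2 ratio of depleted over sated CPM for immediate early and late activity genes in neuron cluster 10, with the tick for all cells, the grey line for its 95% counting interval (a line that reaches the edge has no finite bound) and points for set numbers 1 and 2. Vgf, Cdkn1a and Fos have ratios of 78.4, 68.7 and 48.1, and Jun lies near 0.

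In the mm10 (GRCm38) annotation GENCODE vM21, which may not be the release the authors used, these protein-coding genes lie at the following whole-gene positions. Fos spans chromosome 12 from 85473890 to 85477273, Vgf chromosome 5 from 137026392 to 137033351, Cdkn1a chromosome 17 from 29090976 to 29100727 and Bdnf chromosome 2 from 109674700 to 109727007. Cited1 spans chromosome X from 102247381 to 102252181, Mfge8 chromosome 7 from 79133768 to 79149060, Pnoc chromosome 14 from 65400673 to 65425472 and Ptger3 chromosome 3 from 157566892 to 157645888. The tables give gene symbols alone, and the symbol Fam46a has no entry in that release.

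Neuron cluster 3, a Slc17a6-Etv1 cluster led by Grp, C1ql2 and Gal with Rxfp1 at 683 CPM in sated cells, went the other way. Fos had 46 UMIs in sated and 5 in depleted cells, a ratio of 0.0956 (0.0296 to 0.240), with 0.25 (0.057 to 0.867) and 0.027 (0.001 to 0.16) within set numbers 1 and 2. Without depleted replicate 1 it was 0.026 and without replicate 2 it was 0.287 (0.075 to 0.786). Vgf was at 56.4 and 17.2 CPM, a ratio of 0.305 (0.251 to 0.369), and Adcyap1 at 315 and 121. Late activity genes had a median log2 ratio of -0.49 (-0.21 and -0.58 within set numbers 1 and 2), with 0 called over all genes by edgeR and 3 adjusted over the list alone. Of 12 tested, 6 fell more than in other neurons, among them Vgf (difference -2.64, 1.86e-07), Bdnf (-2.77, 2.62e-04), Crem (-1.48, 6.45e-06) and Scg2 (-0.85, 6.45e-06). With the cells of cluster 10 left out of the other neurons it was again 6, with Vgf at -2.25, Bdnf at -1.84 and Scg2 at -0.75. The immediate early genes had a median of -0.47 (-0.02 and -0.63), and Fos fell more than in other neurons (-3.99, 0.00276). Rxfp1 was at 683 and 287 CPM with a difference from other neurons of 0.04 (0.986). No gene was called in the cluster itself by edgeR, 0 of 13629 with 592 at an unadjusted p under 0.05, or by DESeq2 (0). The sated sets as 2 libraries gave 126 with the set-number block, 83 higher and 43 lower, and 0 without it.

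Neuron clusters 8 and 9, which express Pdyn, had higher late activity medians without a call over all genes. Vgf was at 12.8 and 55.9 CPM in cluster 8, a ratio of 4.38 (3.33 to 5.81), and at 15.1 and 83.8 in cluster 9, a ratio of 5.56 (4.04 to 7.81). It rose more than in other neurons in both (differences 1.42, 2.37e-08, and 1.75, 1.78e-10). Late activity genes had a median log2 ratio of 0.82 in cluster 8 and 0.81 in cluster 9, with 0 called over all genes and 3 and 5 adjusted over the list alone. Fos had ratios of 1.77 (0.748 to 4.32) and 2.65 (0.819 to 11.2) there, so that no difference was detectable at this depth. The Fos ratio was 4.69 (2.27 to 10.9) in the GABAergic-like cluster 5, with 1.89 (0.509 to 10.4) and 6.40 within set numbers 1 and 2, and 0.254 (0.101 to 0.562) in cluster 4. The value in cluster 4 depended on the clustering, at 0.745 (0.485 to 1.13) at lower resolution and 0.905 (0.57 to 1.43) after clustering without the changed genes, and was 0.42 (0.068 to 1.97) with cells thinned. Fos had a ratio of 0.848 (0.705 to 1.02) in cluster 1, the largest GABAergic-like cluster, with opposite directions of 2.02 (1.22 to 3.47) and 0.743 (0.602 to 0.914) within set numbers 1 and 2.

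In the remaining clusters edgeR called few genes that held within both set numbers, and none of their calls on the main sums was shared by DESeq2 (0 in clusters 5, 7 and 12) or by edgeR with the sated sets as 2 libraries (0 in each). In cluster 5 it called 18 genes, 16 higher and 2 lower, of which AY036118 (higher) and the carbonic anhydrase gene Car1 (lower, 36.4 to 8.83 CPM) passed 2-fold within both. In this cluster 0 were called without doublets or with cells thinned and 1 at higher resolution, but 18 in cells with at least 1000 genes and 27 at lower resolution. In cluster 12, whose leading genes Apoe and Pla2g7 are also glial, it called 17, of which Plxdc1 rose and Pdzrn4 and Ccdc91 fell within both. Here 17 were called in cells with at least 1000 genes, 10 without doublets, 3 thinned and 0 at higher resolution. In cluster 7 it called 3, of which AY036118 and the haemoglobin gene Hba-a1 did. In clusters 1, 2, 4, 6, 8, 9 and 11 it called 0 each, with 418, 360, 529, 636, 514, 444 and 146 genes at an unadjusted p under 0.05, and DESeq2 called 1 in clusters 1 and 8 and 0 in the other 5. With the sated sets as 2 libraries and the set-number block edgeR called 83, 54, 67, 0, 28, 43 and 11 in these 7 clusters, and 0, 35 and 8 in clusters 5, 7 and 12.

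**Figure D3:**
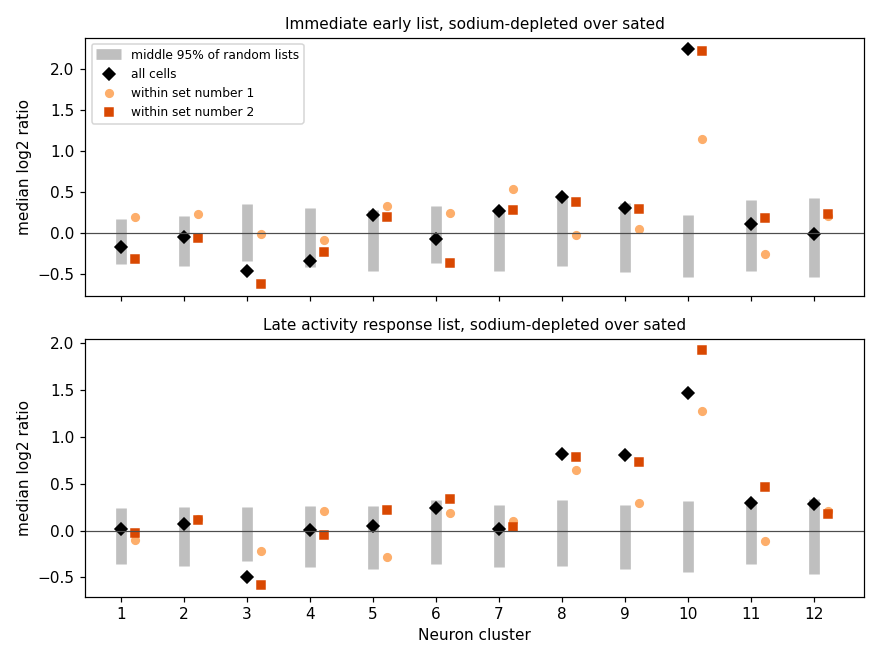
Median log2 ratio of depleted over sated CPM of fixed gene lists per neuron cluster, with diamonds for all cells, points for set numbers 1 and 2 and grey bars for the middle 95% of random lists matched on expression. The immediate early median of 2.24 and the late activity median of 1.47 in cluster 10 lie above their grey bars.

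The all-cell tables asked whether cell types other than neurons differ between the conditions. Vascular leptomeningeal fibroblast-like cells had the most edgeR calls on the main sums, though 0 genes were called there without doublets, at higher resolution or with the sated sets as 2 libraries, and DESeq2 called 3. Of 52 genes edgeR called 41 higher and 11 lower, and 16 passed 2-fold within both set numbers, among them the acute-phase genes Lcn2 and Saa3, the chemokine genes Ccl2 and Cxcl10 and the interferon-induced Isg15. Lcn2 was at 0 and 2.97 CPM in sated sets 1 and 2 and 10.9 and 469 in depleted replicates 1 and 2, a rise of 6.96 ± 0.695 (1.08e-19). Saa3, with no UMI in sated cells, was at 14.5 and 164 (7.98e-22), so that replicate 2 carried most of both. Ccl2 rose by 3.54 ± 0.57 (5.02e-07), from 25.9 and 98.8 to 1178 and 506 CPM. Coch, an extracellular matrix gene, fell from 150 and 151 to 26.6 and 33.9, by -2.22 ± 0.373 on the log2 scale (2.27e-06). The interferon list had a median of 1.05 there, 0.01 and 2.02 within set numbers 1 and 2, with 1 called over all genes and 8 adjusted over the list alone.

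In oligodendrocyte precursor-like cells edgeR called 36 genes, 18 higher and 18 lower, and 9 of them, 3 higher, passed 2-fold within both set numbers. DESeq2 called 0, edgeR with the sated sets as 2 libraries 0, and edgeR with cells thinned 9, 8 higher and 1 lower. The class held 94 and 27 cells in sated sets 1 and 2 and 127 and 82 in depleted replicates 1 and 2. The cell-division genes Ube2c, Ccnb1, Prc1, Top2a and Cenpf were among the lower ones. Ube2c was at 14.7 and 443 CPM in sated sets 1 and 2 and at 2.20 and 0 in depleted replicates 1 and 2 (-6.74 ± 0.681, 4.57e-19), and Ccnb1 at 66.4 and 196, then 2.20 and 0 (-6.21 ± 0.766, 1.25e-12). The highest levels thus came from the 27 cells of sated set 2, and whether the share of dividing cells differed was not tested. In T or NK cell-like cells Chgb, a secretory granule gene, rose from 14.7 and 14.2 to 250 and 193 (3.91, 0.0202) and Ccl2 by 3.99 (0.0314), 2 of 3 calls, with 0 by DESeq2 and 0 with the sated sets as 2 libraries. Chgb was also among the leading genes of unnamed cluster 3 of all cells. Free RNA from other cells was not measured, so it cannot be told apart from Chgb made by this class. In oligodendrocyte-like cells 18 genes were called, against 0 by DESeq2 and 0 with the sated sets as 2 libraries, and the phosphatase gene Inpp5a fell from 139 and 68.3 to 31.95 and 16.1 (-2.24, 0.00123). In microglia-like cells 18 were called, and Mfn1, a mitochondrial fusion gene, fell from 83.0 and 36.9 to 20.0 and 9.85 (-2.25, 0.00101), with 0 calls by DESeq2, without doublets or with the sated sets as 2 libraries. Perivascular macrophage-like cells had 2 calls, with 1 by DESeq2, 0 without doublets and 0 with the sated sets as 2 libraries, and Pkp1 among them was seen in sated set 1 alone (60.4 CPM against 0 in set 2).

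Glucocorticoid response genes had medians of 0.99 in oligodendrocyte-like, 0.45 in microglia-like, 0.40 in astrocyte-like and 0.27 in ependymal-like cells. Within set numbers 1 and 2 these were 0.95 and 0.92, 0.76 and 0.52, 0.23 and 0.65, and 0.41 and 0.33. Astrocyte-like, endothelial-like and ependymal-like cells had 0 genes called by edgeR, with 134, 192 and 106 at an unadjusted p under 0.05 and 0, 1 and 0 by DESeq2, and the set-number block gave 0, 13 and 15. By size alone the 18 classes tested gave 3989 genes in sum, from 21 in ependymal-like to 631 in T or NK cell-like cells, a class of 121 sated cells, and without depleted replicate 1 or 2 they gave 8284 or 5345. Neuron-like cells were 22.7% (22.1 to 23.3) of sated and 20.4% (19.9 to 20.8) of depleted cells, with 17.3% and 31.9% in sated sets 1 and 2 and 18.7% and 21.97% in depleted replicates 1 and 2, so that the conditions differed by less than the sated sets. Astrocyte-like cells were 6.98% and 6.89%, endothelial-like cells 5.79% and 5.23% and ependymal-like cells 6.92% and 7.87%. The sated sets differed by more here too, with endothelial-like cells at 6.76% and 4.14% in sets 1 and 2 and ependymal-like cells at 8.64% and 3.98%, against 5.93% and 4.55%, and 9.13% and 6.66%, in depleted replicates 1 and 2.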

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

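All tests in this part, of differences between neuron clusters and of explanations, were chosen after the result was seen. No group had enough samples to look for a sample far from the others. The change with sodium depletion differed between a neuron cluster and the other neurons, by a test of the difference itself, for 35, 3, 76, 52, 26, 75, 12, 58, 31, 663, 58 and 11 genes in clusters 1 to 12 in that order. With the sated sets as 2 libraries the counts were 11, 3, 66, 18, 15, 11, 4, 26, 38, 694, 6 and 12, so that those of clusters 1, 4, 5, 6, 7, 8 and 11 depend on that choice. The log2 difference in cluster 10 was 5.64 for Fos, 5.92 for Vgf and 2.37 for Bdnf. For Vgf it was -2.64 in cluster 3, 1.42 in cluster 8 and 1.75 in cluster 9.

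Immediate early and late activity genes were higher in depleted cells of neuron cluster 10. Sorting of cells into the cluster by responding genes is argued against by a Fos ratio of 59.0 (22.8 to 218) after clustering again without the genes that differed, with an overlap of cells of 0.866. A difference between whole libraries, free RNA included, is argued against by 11 of 15 immediate early genes. These rose more than in other neurons of the same libraries. With every cell thinned the Fos ratio was 32.1 (5.45 to 1300). Random thinning keeps each cell's expected fraction of Fos UMIs, so this ratio cannot decide on depth. The share of cells with a Fos UMI does depend on depth. After thinning it was still higher in depleted cells, as given above, which argues against depth for that share. Injection and handling stay open, since 0 sated samples have an injection in their labels, so that these cannot be told apart from the loss of sodium. A candidate explanation is thus a response of these Ptger3-expressing, Agtr1a-expressing neurons to the whole treatment, as a hypothesis found and tested on the same libraries.

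The 40 genes higher in all neurons by size differed between the conditions mainly within set number 2. Sodium depletion as the cause of the whole group is argued against by an upper quartile of 0.44 (log2) within set number 1, where the median was 0.26 against 2.14 within set number 2. The genes were chosen by the pooled ratio, in which set number 2 holds most UMIs, so the selection itself favours a higher value there. A property of depleted replicate 2 may be part of the source. In 10 of 10 classes with a non-neuronal name the median difference between the depleted libraries was over 50% of the 0.88 in neurons. That 0.88 is well under the 2.14 within set number 2, so replicate 2 lying above replicate 1 covers only part of it. The sated sets were not compared for these genes, so a property of sated set 2 is not excluded. A first bound of 2-fold was reached in 4 of 10 classes and decides nothing, because the median in neurons themselves lies under it. Bdnf and Anxa2, above 2-fold within both set numbers, are exceptions. They led the genes of cluster 10 over all its cells, but were not among the leading genes of its sated cells. Bdnf rose more in cluster 10 than in other neurons, by 2.37 (log2), so that cluster carried part of its pooled rise. Ratios of these genes without cluster 10 are not given here, and what caused the rise stays open.

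Late activity genes were lower in depleted cells of neuron cluster 3. A difference between whole libraries is argued against by 6 of 12 genes that fell more than in the neurons outside clusters 3 and 10. With every cell thinned the median over all 12 measured genes of the list was -0.67 (log2), against -0.49 before. Random thinning keeps each cell's expected fraction of a gene's UMIs, so this median cannot decide on depth. A difference between set numbers stays open and cannot be told apart from an effect of the treatment, since 5 of the 8 genes that were lower over all cells were lower within both set numbers. Lower activity of the neurons of cluster 3 after sodium depletion might explain the values, as a hypothesis, with injection and handling again untested. Rxfp1 does not set this cluster apart. Its mean CPM per cell was 411.6 in cluster 3, 361.6 in cluster 6 and 333.2 in cluster 4. The Fos ratio was 1.28 (0.768 to 2.14) in cluster 6, and 0.254 in cluster 4, where it depended on the clustering.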

How the results depend on the processing

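Tests on the cell sets taken apart, on single set numbers, with equal weight per cell set, without the cells of cluster 10 and after clustering again were chosen after the data were seen, as were the edgeR counts under other selections of cells, and the other alternatives before the data were examined. Among values that answer a comparison 78 stayed within their bounds, 64 moved, and 1 changed direction among values whose main interval or percentile set them apart from no change. Values near no change crossed it in several settings and count among those that stayed or moved. The number of genes past the rule of size in neurons, 66, was 40 at a minimum of 50 CPM, 146 at 5, 907 with no minimum, 776 at 1.5-fold, 31 with every cell weighing the same, 39 thinned, 25 with cell sets weighted equally, 7 in set number 1, 182 in set number 2, and 105 to 287 without a replicate. In cluster 10 the 536 became 250, 1144 and 1327 at those 3 minimums, 2105 at 1.5-fold, 841 in set number 2 and 675 to 976 without a replicate. Over the cell classes the 3989 became 1563, 7447 and 10970, 14190 at 1.5-fold, 13213 in set number 2 and 5345 to 8284 without a replicate. By edgeR the 0 genes in neurons became 4 with DESeq2 and 154 with the set-number block, and the 7 in cluster 10 became 18 with DESeq2, 400 with the block, 35 without doublets, 38 thinned and 32 after clustering without changed genes. The immediate early median in neurons, 0.08, was 0.19 with median-of-ratios factors, 0.09 in cells with at least 1000 genes, 0.08 without doublets, 0.33 thinned, -0.06 in neuron-like clusters, 0.25 with equal sets, 0.32 and 0.03 in set numbers 1 and 2, 0.07 with members at 5 CPM or more, and -0.22 without the cells of cluster 10. In the GABAergic-like class the -0.08 became 0.04 with median-of-ratios factors, 0.12 with every cell weighing the same, 0.29 thinned, 0.17 with equal sets, 0.41 and -0.18 in set numbers 1 and 2, and -0.06 to -0.04 without a replicate. In the Slc17a6-Etv1 class the 0.27 became 0.37 with median-of-ratios factors, 0.32 thinned, 0.25 at lower resolution, 0.3 with equal sets, 0.21 in set number 2, 0.14 with members at 5 or more, 0.3 to 0.32 without a replicate, and -0.27 without the cells of cluster 10. The Fos ratio over all neurons became 0.918 without those cells. In cluster 10 the 2.24 became 1.52 thinned and 1.14 in set number 1. There the Fos ratio, 48.1, was 32.1 thinned, 59.0 after clustering again, 30.4 with equal sets, 17.3 and 70.7 in set numbers 1 and 2, and 39 to 51.6 without a replicate. Where a number fell or rose with a stricter or looser minimum the construction is the cause, and in the other cases the cause was not tested. Lower and higher resolution returned the same cells for cluster 10. With a depleted replicate left out edgeR has 0 residual degrees of freedom, so only the value was taken. No paired analysis was possible because the labels give the groups fewer than 2 shared replicate numbers, and the set-number block above rests on cell names that no label says pair the libraries. Among single genes and lists 1352 values stayed, 387 moved, 1 changed direction by the same measure, and 293 lost and 5 gained their call. In simulated neurons edgeR recovered 9 of 50 changes of 2-fold and 49 of 50 of 4-fold, with 36 false calls.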

Other observations

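The test of difference between cluster 10 and other neurons, chosen after the data were seen, also covered genes outside the fixed lists, and those named were picked from its result. Sox4 and Sox11, transcription factor genes of immature neurons, were at 124 and 111.5 CPM in sated and 26.1 and 33.4 in depleted cells of cluster 10, and fell more than in other neurons (adjusted p 2.44e-08 and 4.12e-08). Robo1, an axon guidance receptor gene, was at 310 and 88.9 CPM (1.54e-20), Igfbp5, which binds insulin-like growth factors, at 61.9 and 18.9 (2.61e-15), and the matrix genes Adamts2 and Vcan at 38.8 and 3.27 and at 53.0 and 12.3 (1.51e-13 and 2.77e-08). Tenm2, an adhesion gene of synapses, was at 45.4 and 5.80 (2.06e-10), and Tbr1, a glutamatergic transcription factor gene, at 160 and 45.7 (0.00924). Nptx1, which encodes a synaptic pentraxin, was at 2.31 and 20.3 CPM and rose more than in other neurons (3.86e-13), as did Npr1, the receptor of atrial natriuretic peptide, at 22.7 and 53.3 (4.76e-09). In cluster 3 Igfbp5 went the other way, at 13.9 and 41.9 (0.0335).

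In Slc17a6-Etv1 cluster 4 the circadian clock genes had a median log2 ratio of 0.64 between depleted and sated cells, 0.47 and 0.62 within set numbers 1 and 2, with 2 members beyond other neurons over all genes and 4 adjusted over the list alone. Among all cells, a cluster led by C1ql1, Bdnf and Rprm, of whose cells 81.8% are in the authors' neuron tables, had medians of 0.95 for immediate early and 1.07 for late activity genes, with 0.92 for the first within each set number. Its sated cells were led by C1ql1, Fam19a1 and Ptger3, as in neuron cluster 10, and by Rprm, Cbln4 and Brinp3, as in neuron cluster 9. It may hold largely the same cells, so these medians are not independent of the result in cluster 10. Unnamed cluster 3 of all cells made up 6.87% of sated and 11.4% of depleted cells, but 7.54% and 5.72% in sated sets 1 and 2 and 7.83% and 14.7% in depleted replicates 1 and 2. The largest unnamed cluster, led by Ucma, Lpl and Cldn3, made up 28.7% and 22.9%.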
